A study of Homo sapiens with 9 samples.

How the data were processed

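Total RNA was extracted for sequencing from foregut cells at day 6 of directed differentiation of BU3 NGPT. This human induced pluripotent stem cell line carries fluorescent reporters at NKX2-1 (EGFP) and TP63 (tdTomato). The 3 dose groups were no dorsomorphin (0 µM), 1 µM and 2 µM, with 3 libraries each. Dorsomorphin is a small molecule that inhibits BMP type I receptors. The doses of 1 compound cannot tell effects through these receptors apart from effects of any other action it has. Per the labels' protocols, cells were lysed in QIAzol, RNA was purified on RNeasy columns with removal of DNA, and libraries were made with the NEBNext Ultra II RNA kit. The labels number the libraries of each dose but do not say that they came from separate differentiations, so p-values measure only the spread between these libraries, which may be technical.

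The deposited values are whole-number read counts per gene that the authors did not normalize. Per the submitters' processing notes, featureCounts of the Subread package counted reads on GRCh38, and edgeR and limma were used. Their versions, the aligner, the annotation release, and whether counting used the strand are not given in the sources used here. Reads from overlapping and antisense genes can therefore not be told apart, and genes with close copies (such as CSH1 and CSH2, or the PSG family) are uncertain where reads map to several copies. Between 58.8% and 66.2% of the counts from 1 to 10 were even numbers, as if both mates of many read pairs had been counted. Counting error is then larger than the totals imply.

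The table held 33551 entries: 33538 genes, 2 reporters and 11 viral reading frames. The viral entries summed to 8 counts, all in a single library, and stayed out of library sizes and tests. Symbols of 33121 genes were matched to a gene name table, 2159 of them through an older symbol, and 33047 had coordinates in GENCODE release 29 (GRCh38). Coordinates are 1-based and come from that annotation, which may differ from the one used for counting. No column was left unmatched to a sample.

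Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes passing filterByExpr (21090 genes, minimum count 10 and minimum total 15) were scaled by TMM and fitted in 1 quasi-likelihood model with robust dispersion over all 9 libraries, with dose as a factor of 3 levels and no replicate block. The fit had 6 residual degrees of freedom, a common biological coefficient of variation of 0.169 and a median prior of 8.62 degrees of freedom. Tests were 2-sided. Contrasts were 1 against 0 µM, 2 against 0 µM, 2 against 1 µM, any difference among the 3 doses, and the departure of 1 µM from the midpoint of 0 and 2 µM on the log2 scale, which is the departure from a straight line in dose. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called at an adjusted p under 0.05. Levels are CPM values, counts scaled to the TMM-adjusted library size, given as mean ± SD over the 3 libraries of a dose (n = 3). For log2 fold changes and departures, the value after ± is the absolute log2 change divided by the square root of its F statistic. It approximates a standard error and is less reliable where counts are near 0.

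Gene lists for 34 pathways, lineages and processes were tested with camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the 34 lists. Some genes, such as SOX2, HAND1 and GATA3, stand in more than 1 list, so the lists are not independent of each other. Camera with an estimated correlation and fry were run beside it. Some lists had an estimated correlation below the preset and yet a larger adjusted p. For the retinoic acid list at 1 against 0 µM the estimate was −0.0483, and the camera adjusted p went from 4.4e-20 to 0.000996. The larger values of that variant are thus not due to correlation between genes alone. Counts of members that rose or fell are given over all genes tested and also adjusted over the list alone. The lists, the designs, the alternatives and the rule for named genes were fixed before the data were examined. Named genes were the 12 largest rises and 12 largest falls of each comparison (6 each for the departure) among called genes with a higher group mean of at least 5 CPM, for the pairwise comparisons also without overlap between the groups. Added to them were up to 4 members per list with the lowest adjusted p, all members of the BMP target and anterior foregut lists, NKX2-1 and TP63. Genes without a standard symbol were left out by that rule, as were Y-linked genes and XIST. The EGFP reporter, SFTA3, the genes given as highest or lowest at 1 µM other than those the rule names, and the genes counted almost only in 1 library were chosen after their values were seen.

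The gene tests and the list tests were tested on simulated data with known changes, drawn from the real means, dispersions and library sizes. Among genes at 5 CPM or more, 100% of the 4-fold changes were recovered in each of the 3 pairwise comparisons. The 2-fold changes were recovered at 100%, 97.1% and 100%, and the 1.5-fold changes at 75.9%, 88.0% and 83.9%, for 1 against 0, 2 against 0 and 2 against 1 µM. Over tested genes of all levels recovery was lower, at 68%, 70% and 80% for 4-fold, 56%, 74% and 52% for 2-fold and 44%, 46% and 52% for 1.5-fold changes. The 1.2-fold changes were recovered at 4%, 13.8% and 4.17% among genes at 5 CPM or more. Of 20890 unchanged genes, 6, 10 and 4 were called. In each simulated comparison only 50 genes were changed at each fold, so far fewer genes changed than were called in the real data. The adjusted threshold was then stricter, so neither the recovery rates nor the few false calls need carry over to the real comparisons. For the shared 0 µM libraries, all 9 libraries were simulated 20 times from the 0 µM means with no change between groups. Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, library totals, no filter and a filter of 1 CPM in 3 libraries, non-robust dispersion, a stricter threshold, glmTreat against 1.5-fold, a replicate block, the 6 libraries of a pair and each library left out in turn. Halved counts and the removal of 2 libraries together were added after seeing the data. No replicate pair was a duplicate: the chi-square per degree of freedom between libraries of 1 dose was between 14.2 and 85.9. At 2 µM it was 57.7 and 85.9 for the pairs with replicate 1 and 15.7 for the pair without it.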

Results

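RNA sequencing measured transcript levels in foregut cells at day 6 of differentiation of the human line BU3 NGPT, in 9 libraries. The cells had received no dorsomorphin (0 µM), 1 µM or 2 µM of this BMP receptor inhibitor, with 3 libraries per dose. Library totals were 87225057, 87912980 and 86863468 counts at 0 µM. They were 98381604, 110054458 and 99705183 counts at 1 µM and 90739300, 81240319 and 78066910 counts at 2 µM. Mitochondrial transcripts took between 4.03% and 4.80% of the counts of a library. The first principal component held 43.6% of the variance and ordered the groups by dose, with scores of −91.2 to −81.8 at 0 µM, 27.7 to 37.1 at 1 µM and 37.9 to 68.2 at 2 µM. On the second component (14.9%), the libraries of 1 dose were spread at 0 µM (35.4, −36.0 and 1.88) and at 2 µM (−17.2, 58.7 and 47.8), and the 1 µM libraries lay between −38.9 and −21.3. More genes had a count above 0 in the 0 µM libraries (29248, 25487 and 27357) than in the 1 µM libraries (24565, 24127 and 25286), and the 2 µM libraries had 23936, 24765 and 26852. Counts of EGFP were between 102 and 638 per library, and tdTomato had 2 counts in 1 library and 0 in the other 8.

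**Figure D1:**
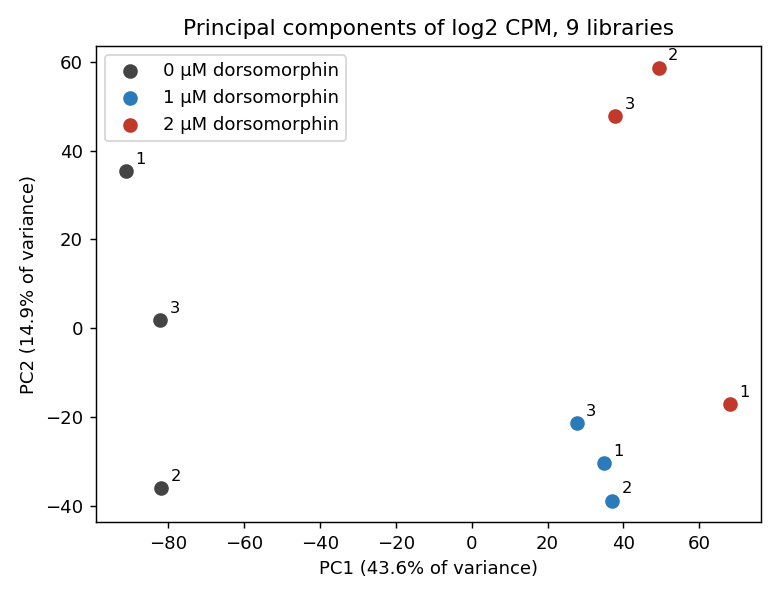
Principal component scores of the 9 libraries on log2 CPM, with component 1 (43.6% of the variance) on the horizontal and component 2 (14.9%) on the vertical axis, 1 point per library marked by dose. The 0 µM libraries lie at −91.2 to −81.8 on component 1, and all libraries with dorsomorphin lie above 27.

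The comparison of 1 µM with 0 µM shows the response to the lower dose. Most genes of the liver lineage fell, with the lowest median change of the 34 lists. AFP, the fetal serum protein alpha-fetoprotein (chromosome 4, 73431138 to 73456174), went from 266 ± 29 CPM without inhibitor to 0.214 ± 0.242 CPM at 1 µM (n = 3 each, log2 fold change −10.22 ± 0.49, adjusted p = 9.6e-07). Most direct targets of BMP signalling fell as well, among them ID2, which encodes an inhibitor of basic helix-loop-helix factors, from 379 ± 26.8 to 132 ± 13.1 CPM. Most transcription factors of the anterior foregut rose, with SOX2 (chromosome 3, 181711924 to 181714436) going from 0.319 ± 0.101 to 10.4 ± 2.3 CPM (log2 fold change 5.02 ± 0.21, adjusted p = 1.3e-10). All 17 DNA replication genes and 5 of 10 retinoic acid response genes rose too.

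Of 16 liver progenitor genes, 15 fell and 1 did not pass the test. Again 15 fell when adjusted over the list alone (median log2 fold change −3.33, camera adjusted p = 1.9e-53). The thyroxine carrier TTR went from 1326 ± 141 to 82.6 ± 13.7 CPM, and APOA1, the main protein of high-density lipoprotein, from 732 ± 69.7 to 33 ± 6.04 CPM (adjusted p = 6.4e-12). HNF4A, a transcription factor of hepatocytes (chromosome 20, 44355700 to 44434596), fell by 2.23 on the log2 scale, from 274 ± 15.8 to 58.6 ± 3.41 CPM. Fibrinogen chain genes were among the largest falls, with FGB at 338 ± 20.4 CPM without inhibitor and 0.473 ± 0.585 CPM at 1 µM and FGG at 25.1 and 0.234 CPM. Other large falls were SERPINA1, MTTP, which loads lipid onto lipoproteins, HABP2, the bile acid enzyme AKR1D1, PRODH2, BCO1 and the retinaldehyde dehydrogenase ALDH1A1 (117 ± 10.7 to 1.45 ± 0.616 CPM). The T-box factor gene TBX2 fell from 27.1 ± 2.87 to 0.584 ± 0.204 CPM.

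Among 11 BMP-SMAD target genes, 9 fell, none rose and 2 did not pass, and 10 fell when adjusted over the list alone (median log2 fold change −0.87, camera adjusted p = 6.5e-13, adjusted p = 0.0360 with an estimated correlation). SMAD6 (chromosome 15, 66702228 to 66782848), which encodes an inhibitory SMAD, fell from 371 ± 21.6 to 99.6 ± 4.44 CPM (log2 fold change −1.90 ± 0.07, adjusted p = 3.9e-11). The other inhibitory SMAD gene, SMAD7, fell from 97.6 ± 7.39 to 39.7 ± 3.77 CPM, MSX2 from 44.5 ± 2.08 to 14.8 ± 2.79 CPM and ID1 (chromosome 20, 31605283 to 31606515) from 488 ± 51 to 295 ± 21.6 CPM (adjusted p = 7.0e-05). ID4 (202 and 185 CPM) and ATOH8 (2.39 and 1.53 CPM) did not pass. Of 11 secreted BMP antagonists, 5 fell and 0 rose (5 when adjusted over the list alone, camera adjusted p = 0.00102), including NOG from 14 ± 0.35 to 0.791 ± 0.307 CPM. That list had an adjusted p = 0.0626 with an estimated correlation. The ligand gene BMP4 rose from 18.5 ± 0.875 to 64.3 ± 2.51 CPM, while BMP2, BMP5 and BMP6 fell. The 15 BMP ligand, receptor and SMAD genes were not called as a list (2 rose, 5 fell, the same when adjusted over the list alone, camera adjusted p = 0.188).

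**Figure D2:**
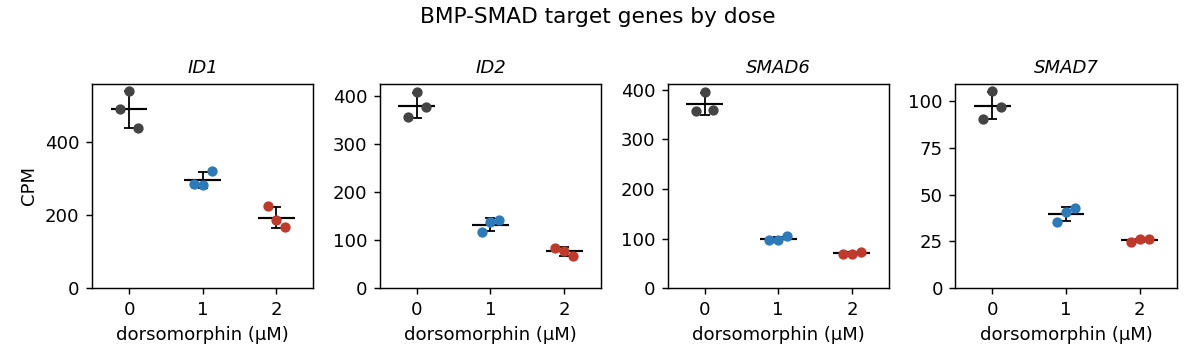
TMM-scaled CPM of ID1, ID2, SMAD6 and SMAD7 against dorsomorphin dose (0, 1 and 2 µM), with 1 point per library and the mean ± SD of 3 libraries. Each of the 4 genes has a lower mean at 1 µM than at 0 µM and its lowest mean at 2 µM, such as 379, 132 and 76.5 CPM for ID2.

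Of 14 anterior foregut transcription factor genes, 10 rose, 1 fell and 3 did not pass, with 10 up and 1 down when adjusted over the list alone (median log2 fold change 1.47, camera adjusted p = 8.8e-16). PAX1, a pharyngeal pouch factor, rose from 0.266 ± 0.259 to 8.02 ± 1.68 CPM, and TBX1 (chromosome 22, 19756703 to 19783593) from 25.4 ± 1.93 to 70.2 ± 4.12 CPM (log2 fold change 1.47 ± 0.09). OTX2, a factor of anterior head tissue, rose from 113 ± 4.79 to 313 ± 26.1 CPM and EYA1 from 4.17 ± 0.843 to 27.3 ± 2.53 CPM. FOXA1 fell from 61.4 ± 3.66 to 37.1 ± 4.88 CPM, and FOXA2 (299 ± 10.2 and 279 ± 11.8 CPM) did not pass. Of 10 retinoic acid response genes, 5 rose and 2 fell (6 and 2 when adjusted over the list alone, camera adjusted p = 4.4e-20). The retinoic acid degrading enzymes CYP26A1 (chromosome 10, 93073475 to 93077890) and CYP26C1 went from 0.335 ± 0.101 to 38 ± 2.9 CPM and from 0.0416 ± 0.053 to 61.2 ± 6.68 CPM. CYP26C1 had 9, 0 and 2 counts in the 0 µM libraries, so its log2 fold change of 10.44 ± 0.26 rests on few counts at baseline. The receptor gene RARB rose from 8.39 ± 1.4 to 43.6 ± 3.05 CPM.

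All 17 DNA replication genes rose (17 when adjusted over the list alone, median log2 fold change 1.15, camera adjusted p = 8.2e-29), such as CDC6 from 18.6 ± 1.67 to 58.9 ± 4.01 CPM and MCM6, a subunit of the replicative helicase, from 61.1 ± 3.02 to 172 ± 10.03 CPM. All 18 cell division genes rose as well (18 when adjusted over the list alone), by a median of 0.64 on the log2 scale. Their list test had an adjusted p of 4.5e-09, and adjusted p = 0.238 with an estimated correlation. Other large rises were DMBX1 (0.466 ± 0.348 to 94 ± 3.78 CPM), a homeobox gene, NRP2, a semaphorin and VEGF co-receptor (8.21 ± 1.05 to 242 ± 36.7 CPM), SHISA2 (11.4 ± 1.33 to 255 ± 19.6 CPM), EYA2, NEBL, FAM241A, PLPPR5 and PODN.

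Lists of several other lineages and pathways were also called at 1 µM, each losing the call with an estimated correlation. Of 9 pancreas and duodenum genes, 1 rose and 5 fell (1 and 6 when adjusted over the list alone) (camera adjusted p = 0.000262, adjusted p = 0.0573 with an estimated correlation). Of 14 cardiac and lateral plate mesoderm genes, 3 rose and 5 fell (the same when adjusted over the list alone), and PDGFRA went from 202 ± 11.5 to 20.3 ± 3.1 CPM (camera adjusted p = 0.000517, adjusted p = 0.0536 with an estimated correlation). In the endothelium and blood list 5 of 14 fell (6 when adjusted over the list alone, camera adjusted p = 0.0308, adjusted p = 0.342 with an estimated correlation). Most of its members were below 5 CPM. Thinned to equal depth, 25371 to 29147 genes of all levels were detected in the 0 µM libraries and 23827 to 25048 in the 1 µM libraries. CDX2 fell from 7.92 ± 0.474 to 0.579 ± 0.0954 CPM in the mid and hindgut list, where 2 of 5 measured genes fell (2 when adjusted over the list alone, camera adjusted p = 0.0433, adjusted p = 0.216 with an estimated correlation). Of 13 WNT target genes 3 rose and 7 fell (the same when adjusted over the list alone, camera adjusted p = 0.0220, adjusted p = 0.108 with an estimated correlation), with SP8 down from 60.3 to 8.01 CPM and DKK1 up from 26.2 to 64.3 CPM. Of 13 notch pathway genes 2 rose and 6 fell (3 and 6 when adjusted over the list alone, camera adjusted p = 0.0198, adjusted p = 0.238 with an estimated correlation). SIX3 rose from 7.29 ± 1.37 to 29.1 ± 2.05 CPM in the neuroectoderm list, where 4 of 12 rose and 1 fell (the same when adjusted over the list alone, camera adjusted p = 0.0168, adjusted p = 0.230 with an estimated correlation). Of 11 surface ectoderm and placode genes 4 rose and 0 fell, with SIX4 and EYA2 among the rises (4 when adjusted over the list alone, camera adjusted p = 4.6e-05, adjusted p = 0.0626 with an estimated correlation).

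In total 5591 of 21090 genes were called at 1 against 0 µM, 2897 up and 2694 down, and 585 rose and 1150 fell by at least 2-fold. The groups did not overlap for 44.3% of genes, where chance gives 10%. Tested against a change of 1.5-fold, 1467 genes were called. By camera with an estimated correlation 5 lists kept their call, at larger adjusted p-values. These were 0.000622 for liver, 0.000996 each for anterior foregut, retinoic acid and DNA replication and 0.0360 for BMP targets. The mid and hindgut list lost its call without 0 µM replicate 1, 2 or 3 (adjusted p = 0.0504, 0.0574 and 0.0648) or 1 µM replicate 3 (0.0702) and with camera on limma-voom values (0.0788), with a range of 0.000456 to 0.216 over its alternatives. On limma-voom values the cardiac and lateral plate list (adjusted p = 0.0819, range 3.9e-05 to 0.0819) and the neuroectoderm list (0.168, range 0.000617 to 0.230) also lost theirs.

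The comparison of 2 µM with 0 µM shows the response to the higher dose. Most liver and BMP target genes were again lower and most anterior foregut genes higher. FGB had 338 ± 20.4 CPM at 0 µM and 0.0985 ± 0.0126 CPM at 2 µM (n = 3 each), TTR fell from 1326 ± 141 to 19.7 ± 4.07 CPM, and SOX2 rose from 0.319 ± 0.101 to 38.6 ± 3.59 CPM (log2 fold change 6.92 ± 0.21, adjusted p = 1.8e-12). The homeobox genes SIX3 (7.29 ± 1.37 to 73.9 ± 5.32 CPM) and OTX2 (113 ± 4.79 to 494 ± 12.6 CPM) rose. The heart and gut factor gene GATA4 (chromosome 8, 11676959 to 11760002) fell from 448 ± 23.8 to 67.6 ± 3.87 CPM.

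Of 16 liver progenitor genes 14 fell (15 when adjusted over the list alone) and 0 rose, with a median log2 fold change of −3.96 and a camera adjusted p = 5.1e-48. HNF4A went to 22.5 ± 2.72 CPM and APOA1 to 12.9 ± 1.73 CPM. Large falls outside that list were ALDH1A1 (to 0.297 ± 0.106 CPM), HABP2, CREB3L3, PRODH2, BCO1, AKR1D1, MTTP and the gap junction gene GJB1. Of 11 BMP-SMAD target genes 10 fell, also when adjusted over the list alone (median log2 fold change −1.26, camera adjusted p = 2.9e-17, adjusted p = 0.0168 with an estimated correlation). ID2 had 76.5 ± 8.71 CPM at 2 µM (log2 fold change −2.31 ± 0.10), SMAD6 70.6 ± 2.1 CPM and ID1 193 ± 28.6 CPM, and MSX1 did not pass (1.73 and 1.16 CPM). Of the BMP ligand, receptor and SMAD genes 2 of 15 rose and 6 fell (the same when adjusted over the list alone, camera adjusted p = 0.0136, adjusted p = 0.194 with an estimated correlation), BMP4 rising to 82.6 ± 7.38 CPM and BMP2 falling from 325 ± 13.3 to 94.2 ± 0.961 CPM. Of the 11 secreted antagonists 3 rose and 5 fell (the same when adjusted over the list alone, camera adjusted p = 0.00218, adjusted p = 0.0890 with an estimated correlation), NOG going to 0.309 ± 0.0332 CPM and FST from 7.56 ± 0.678 to 11 ± 1.55 CPM.

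Anterior foregut factors showed 10 rises and 1 fall among 14, also when adjusted over the list alone (median log2 fold change 2.09, camera adjusted p = 1.4e-17). TBX1 reached 113 ± 10.9 CPM (adjusted p = 4.1e-11) and PAX1 13.5 ± 2.07 CPM. In the retinoic acid list 6 of 10 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 1.4e-17). CYP26A1 reached 118 ± 10.1 CPM and CYP26C1 287 ± 31 CPM. DNA replication genes rose in 16 of 17 cases (17 when adjusted over the list alone, camera adjusted p = 7.4e-23) and cell division genes in 16 of 18 (17 when adjusted over the list alone, camera adjusted p = 0.000676, adjusted p = 0.414 with an estimated correlation). Further large rises were DMBX1 (to 221 ± 11.2 CPM), NRP2 (to 606 ± 97.6 CPM), FGF8, the growth factor of pharyngeal and head signalling centres (0.322 ± 0.112 to 15.9 ± 2.12 CPM), FOXI2, SOX3, SHISA2, EDNRB and GSC.

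Of 9 pancreas and duodenum genes 6 fell and 1 (SOX9) rose, also when adjusted over the list alone (camera adjusted p = 1.6e-06). Of 14 cardiac and lateral plate mesoderm genes 6 fell and 3 rose (7 and 3 when adjusted over the list alone, camera adjusted p = 1.5e-05), PDGFRA going to 7.55 ± 0.997 CPM. In the mid and hindgut list 4 of 5 fell (4 when adjusted over the list alone, camera adjusted p = 0.00687, adjusted p = 0.0890 with an estimated correlation). Definitive endoderm genes split into 8 falls, among them SOX17 from 90.8 ± 4.95 to 20.1 ± 3.04 CPM, and 4 rises, among them CXCR4 from 28 ± 0.61 to 121 ± 9.55 CPM (the same when adjusted over the list alone, camera adjusted p = 0.0110, adjusted p = 0.194 with an estimated correlation). Neuroectoderm genes rose in 6 of 12 cases and fell in 1 (7 and 1 when adjusted over the list alone, camera adjusted p = 0.000485, adjusted p = 0.0899 with an estimated correlation). Of 13 lung and thyroid genes 6 rose and 3 fell (6 and 4 when adjusted over the list alone, camera adjusted p = 0.0315, adjusted p = 0.138 with an estimated correlation). The rises included NKX2-1 and the Iroquois genes IRX2, IRX3 and IRX5, which many tissues express. Surface ectoderm genes rose in 3 and fell in 3 of 11 cases (the same when adjusted over the list alone, camera adjusted p = 0.00321, adjusted p = 0.124 with an estimated correlation).

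In the hedgehog list 8 of 10 genes rose and IHH fell from 217 ± 12.9 to 21.7 ± 1.04 CPM (8 and 1 when adjusted over the list alone, camera adjusted p = 0.0450, adjusted p = 0.387 with an estimated correlation). PTCH1, a receptor and target of the pathway, rose from 35.7 ± 1.98 to 117 ± 24 CPM and GLI3 from 2.94 ± 0.352 to 20.7 ± 2.35 CPM. WNT target genes fell in 6 and rose in 2 of 13 cases (the same when adjusted over the list alone, camera adjusted p = 0.0136, adjusted p = 0.0891 with an estimated correlation). Notch genes fell in 7 and rose in 3 of 13 (8 and 3 when adjusted over the list alone, camera adjusted p = 0.0401, adjusted p = 0.264 with an estimated correlation). Amnion and trophoblast genes fell in 6 of 9 cases and ISL1 rose (the same when adjusted over the list alone, camera adjusted p = 0.0238, adjusted p = 0.110 with an estimated correlation). Most measured members of that list, among them CDX2, HAND1, GATA2 and GATA3, also stand in other lists. Some genes of the placenta, chosen after their values were seen, had counts almost only in 2 µM replicate 2, such as CSH1 with 1292 counts against at most 8 in the other libraries, PAPPA with 2609 against at most 111 and CGA with 445 against at most 16. PAPPA, tested, was not called at 2 against 0 µM (adjusted p = 0.122).

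At 2 against 0 µM 6702 genes were called, 3466 up and 3236 down, and 965 rose and 1316 fell by at least 2-fold. The groups did not overlap for 41.7% of genes, where chance gives 10%. Tested against a change of 1.5-fold, 2142 genes were called. By camera with an estimated correlation 7 lists kept their call, at larger adjusted p-values. These were 0.00142 each for liver, anterior foregut and retinoic acid and 0.00222 for DNA replication. They were 0.0168 each for BMP targets and the cardiac list and 0.0183 for the pancreas list. The amnion and trophoblast list lost its call without 0 µM replicate 3 (adjusted p = 0.0510), 2 µM replicate 1 (0.0709) or 2 µM replicate 3 (0.0623), with a range of 3.1e-05 to 0.110 over its alternatives. The notch list lost it without 2 µM replicate 1 (0.0693) or 3 (0.0623), with a range of 0.000113 to 0.264, and the hedgehog list without 0 µM replicate 2 (0.0912) or 3 (0.0609) or with halved counts (0.0723), with a range of 0.00279 to 0.387. With camera on limma-voom values the lung and thyroid list (adjusted p = 0.237, and 0.0531 with halved counts, range 8.2e-05 to 0.237), the surface ectoderm list (0.417, range 8.7e-05 to 0.417) and the secreted antagonists (0.0657, range 2.2e-05 to 0.0890) lost their calls.

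**Figure D3:**
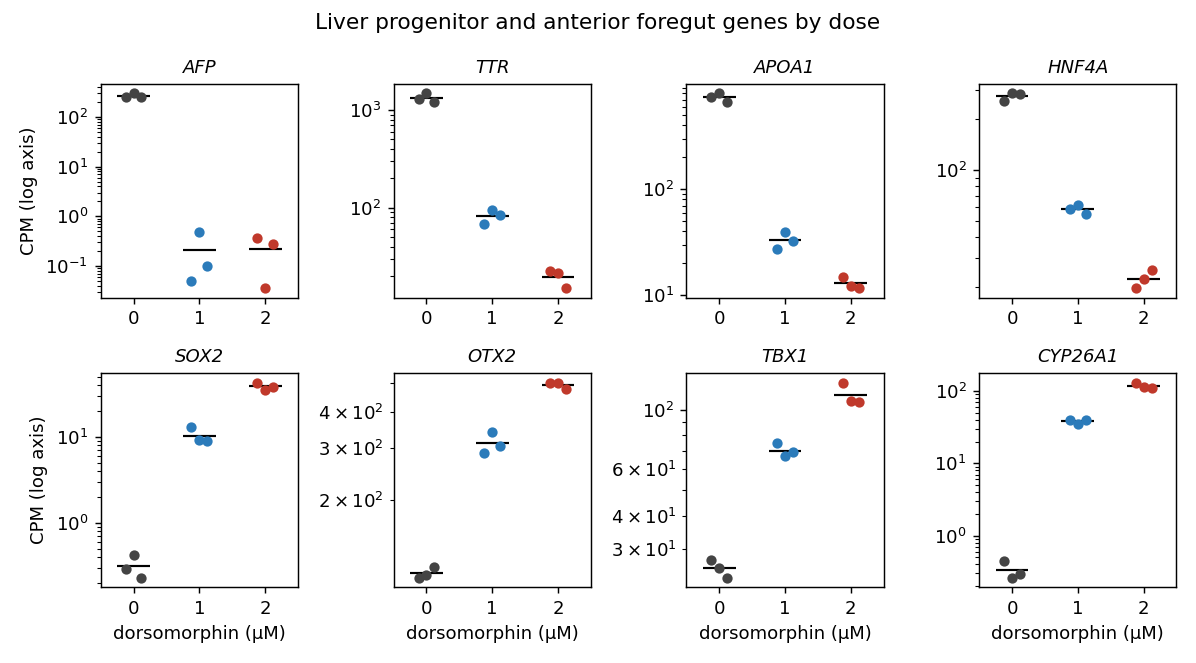
TMM-scaled CPM on a log axis of the liver lineage genes AFP, TTR, APOA1 and HNF4A and of SOX2, OTX2, TBX1 and CYP26A1 against dorsomorphin dose (0, 1 and 2 µM), with 1 point per library and a mark at the mean of 3 libraries. The means of TTR go from 1326 through 82.6 to 19.7 CPM and those of SOX2 from 0.319 through 10.4 to 38.6 CPM.

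The comparison of 2 µM with 1 µM tests the second dose step itself. In this step 7 of 16 liver genes and 7 of 11 BMP target genes fell, and 5 of 14 anterior foregut genes rose. TTR fell from 82.6 ± 13.7 to 19.7 ± 4.07 CPM (n = 3 each, log2 fold change −2.07 ± 0.15, adjusted p = 5.4e-07), HNF4A from 58.6 ± 3.41 to 22.5 ± 2.72 CPM and ID2 from 132 ± 13.1 to 76.5 ± 8.71 CPM (log2 fold change −0.78 ± 0.09). SOX2 rose from 10.4 ± 2.3 to 38.6 ± 3.59 CPM (log2 fold change 1.90 ± 0.15, adjusted p = 9.8e-07). AFP was near its floor at both doses, at 0.214 ± 0.242 and 0.223 ± 0.167 CPM.

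Of 16 liver progenitor genes 7 fell and 0 rose (8 and 1 when adjusted over the list alone, median log2 fold change −0.68, camera adjusted p = 4.7e-16). Of 11 BMP-SMAD target genes 7 fell and 4 did not pass, ID3, BAMBI, MSX1 and ATOH8 (9 fell when adjusted over the list alone, median log2 fold change −0.50, camera adjusted p = 1.9e-11, adjusted p = 0.0317 with an estimated correlation). Of 15 ligand, receptor and SMAD genes 2 rose and 3 fell (2 and 7 when adjusted over the list alone, camera adjusted p = 3.7e-05, adjusted p = 0.0624 with an estimated correlation), including BMP2 from 202 ± 5.16 to 94.2 ± 0.961 CPM. Anterior foregut factors rose in 5 and fell in 1 of 14 cases (6 and 1 when adjusted over the list alone, camera adjusted p = 2.5e-10). The gene that fell was HHEX (198 ± 2.33 to 165 ± 10.5 CPM), but its call was lost in several alternatives, among them the fit of the 6 libraries of this pair (adjusted p = 0.0601) and those with a single library left out. Its adjusted p was 0.0510 without 0 µM replicate 1, 0.0524 without 0 µM replicate 3, 0.0982, 0.119 and 0.119 without 1 µM replicate 1, 2 and 3, 0.138 without 2 µM replicate 2 and 0.102 without 2 µM replicate 3, with a range of 0.00275 to 1 over its alternatives. In the retinoic acid list CYP26A1 and CYP26C1 rose and DHRS3 fell (5 and 1 of 10 when adjusted over the list alone, camera adjusted p = 3.9e-09).

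The largest rises of this step included ANGPT2, an angiopoietin, from 0.337 ± 0.0727 to 7.49 ± 0.413 CPM (adjusted p = 4.3e-07), GSC, a homeobox gene of the organizer and prechordal plate (chromosome 14, 94768216 to 94770230), from 2.71 ± 0.0799 to 21.5 ± 3.73 CPM (log2 fold change 2.99 ± 0.19), EDNRB, an endothelin receptor, from 6.72 ± 1.56 to 32.2 ± 3.97 CPM and FGF8 from 4.39 ± 0.161 to 15.9 ± 2.12 CPM. SOX3, SULF1, AK5 and CAPN6 rose as well. The largest falls included the neuropeptide gene NPY from 61.3 ± 1.31 to 11.6 ± 1.47 CPM, the zinc transporter gene SLC39A5, the axon guidance receptor ROBO2, IHH from 83.2 ± 5.14 to 21.7 ± 1.04 CPM, the cholesterol ester enzyme SOAT2, CPN1, SHD, CYP4X1, RASSF10 and BMP5.

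Pancreas and duodenum genes fell in 4 of 9 cases (6 when adjusted over the list alone, camera adjusted p = 3.0e-08). Cardiac and lateral plate genes fell in 4 of 14 cases with 1 rise (the same when adjusted over the list alone, camera adjusted p = 5.0e-07). Amnion and trophoblast genes fell in 4 of 9 (5 when adjusted over the list alone, camera adjusted p = 4.2e-07), beside the placental counts of 2 µM replicate 2. In the mid and hindgut list 2 of 5 fell (2 when adjusted over the list alone, camera adjusted p = 0.00152, adjusted p = 0.0578 with an estimated correlation). SOX3 and SIX3 were 2 of the 3 rises among 12 neuroectoderm genes (5 up and 1 down when adjusted over the list alone, camera adjusted p = 3.6e-06, adjusted p = 0.0578 with an estimated correlation). Of 14 definitive endoderm genes 2 rose and 7 fell (3 and 7 when adjusted over the list alone, camera adjusted p = 0.0331, adjusted p = 0.243 with an estimated correlation), with a median log2 fold change of −0.12, a mean of 0.02 and a test direction of down. Esophageal and stratified epithelium genes were called as higher with 1 rise, SOX2, and 1 fall among 10 (2 and 1 when adjusted over the list alone, camera adjusted p = 0.00642, adjusted p = 0.0964 with an estimated correlation). TP63, a factor of basal cells, was not called in any comparison and had 0.324 ± 0.116, 0.2003 ± 0.0824 and 0.445 ± 0.108 CPM at 0, 1 and 2 µM.

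Pluripotency genes were called as lower with 2 falls, TDGF1 and L1TD1, among 12 (2 when adjusted over the list alone, camera adjusted p = 0.0331, adjusted p = 0.122 with an estimated correlation). L1TD1 lost its call without both 0 µM replicate 1 and 2 µM replicate 2 (adjusted p = 0.0571, with a range of 2.3e-05 to 1 over its alternatives). Immediate early genes were called as higher with 1 rise among 11 (2 when adjusted over the list alone, camera adjusted p = 0.0331, adjusted p = 0.243 with an estimated correlation). Lung and thyroid genes were called as higher with 3 rises, IRX2, IRX3 and IRX5, and 1 fall, NKX2-1, among 13 (5 and 1 when adjusted over the list alone, camera adjusted p = 0.0331, adjusted p = 0.167 with an estimated correlation). DNA replication genes were called as higher with 1 rise, MCM6, among 17 (1 when adjusted over the list alone, camera adjusted p = 0.0331, adjusted p = 0.243 with an estimated correlation). Cell division genes were called as lower by camera (adjusted p = 0.00642, adjusted p = 0.529 with an estimated correlation) although edgeR called 0 of the 18 members, also when adjusted over the list alone. At an unadjusted p under 0.05 edgeR had 4 of them, and DESeq2 and limma-voom called 0.

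Between 1 and 2 µM 1105 genes were called, 424 up and 681 down, and the groups did not overlap for 19.8% of genes, where chance gives 10%. Tested against a change of 1.5-fold, 179 genes were called. By camera with an estimated correlation 7 lists kept their call, at larger adjusted p-values. These were 0.00943 each for liver, anterior foregut, retinoic acid, cardiac and amnion lists, 0.00957 for pancreas and 0.0317 for BMP targets. Without both 0 µM replicate 1 and 2 µM replicate 2, an alternative chosen after seeing the data, 655 genes were called. Without 2 µM replicate 1, which differed more from the other 2 µM libraries than they did from each other, 1529 were. Several lists lost their call without 1 library. The definitive endoderm list did without 0 µM replicate 3 (adjusted p = 0.0692), 2 µM replicate 2 (0.214) or 3 (0.0536), with a range of 0.00260 to 0.281 over its alternatives, and the pluripotency list without 2 µM replicate 2 (0.0715) or 3 (0.0665), with a range of 0.00427 to 0.122. The DNA replication list did without 1 µM replicate 1 (0.0599) or 3 (0.0596) or 2 µM replicate 1 (0.0943) or 2 (0.0715), with a range of 0.00739 to 0.243. The immediate early list did without 1 µM replicate 1 (0.137) or 2 µM replicate 1 (0.119), with a range of 0.00725 to 0.243, and the lung and thyroid list without 1 µM replicate 3 (0.0890) or 2 µM replicate 3 (0.0536), with a range of 0.0117 to 0.167. Without 0 µM replicate 1 and 2 µM replicate 2 together the definitive endoderm (0.281), pluripotency (0.0758), DNA replication (0.0754) and cell division lists (0.0552, range 0.000128 to 0.529) lost theirs, as did the definitive endoderm list with halved counts (0.0739) and the mid and hindgut list without the low-count filter (0.264, range 0.000732 to 0.264).

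**Figure D4:**
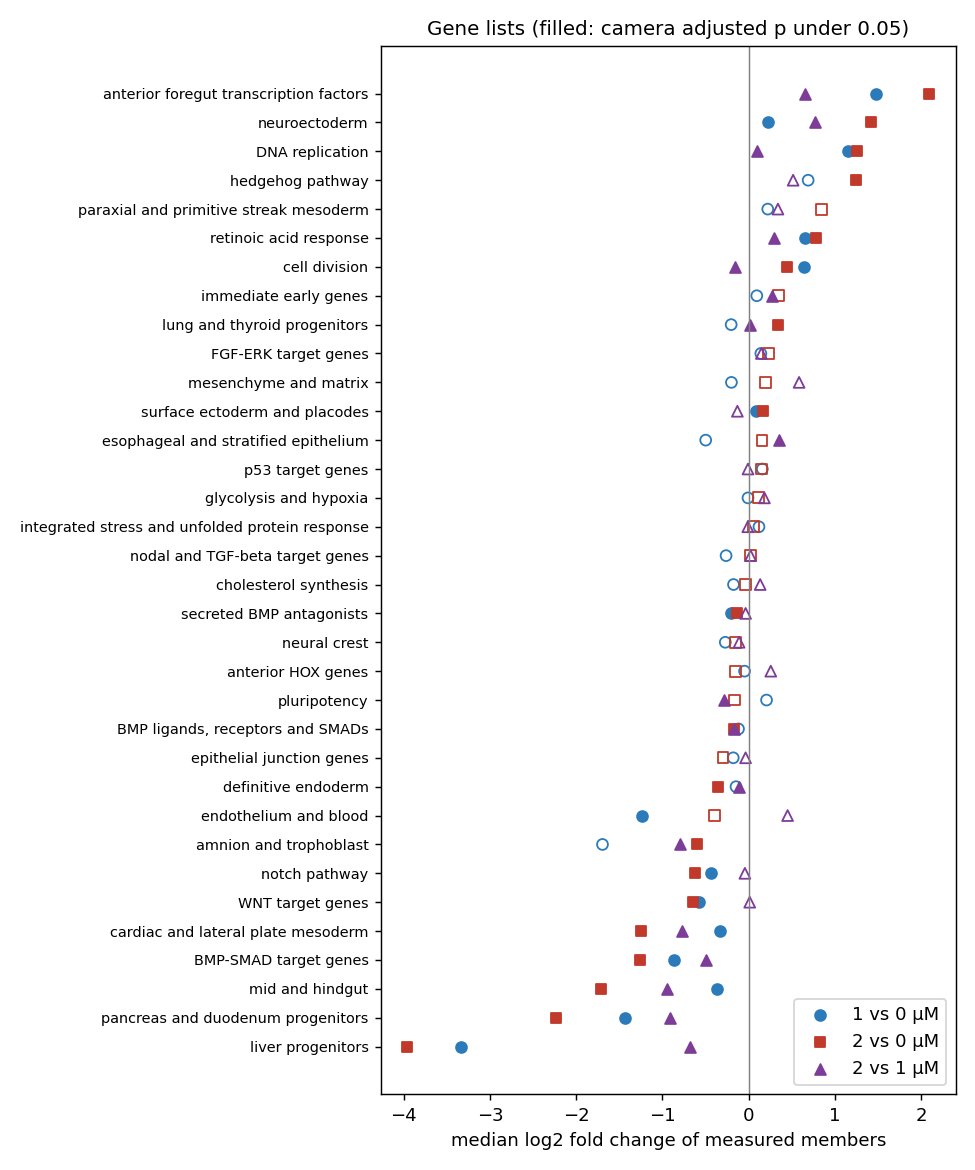
Median log2 fold change of each of the 34 gene lists (horizontal axis) for 1 against 0 µM, 2 against 0 µM and 2 against 1 µM, with a filled symbol where the camera adjusted p (preset correlation 0.01) is under 0.05. The liver progenitor list has the lowest median at 2 against 0 µM, −3.96, and 15, 19 and 17 lists are filled in the 3 comparisons.

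The doses together show how the response was shared out between the steps. Over the 3 doses 6511 genes differed, and 4754 genes were called the same way at 1 and at 2 µM against 0 µM, with 10 called in opposite directions. Both comparisons use the same 0 µM libraries. In 20 simulations of unchanged groups against shared controls 0 genes were called by edgeR in both. Those simulations had at most 1 call at 1 µM and at most 2 at 2 µM, so that overlap of 0 does not measure what shared controls add. Independent lists of the same sizes as the real ones would share 889. The log2 fold changes of all genes, which are not independent replicates, correlated at 0.733 against a simulated median of 0.503 (0.489 to 0.523), with a covariance of 0.753 against 0.122, a difference of 0.631. The same sign was seen in 83.7% of genes against a simulated 66.8%. The 3 controls cannot be split into groups of 2, so part of the excess may come from the shared controls.

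On the log2 scale, most of the change had occurred at 1 µM. Of 2281 genes changed by at least 2-fold at 2 µM, the median had reached 72.6% of its log2 change at 1 µM (quartiles 57.7% and 87.5%). The departure of 1 µM from the midpoint of 0 and 2 µM was called for 1795 genes, 1013 above and 782 below. At 2-fold or more the balance was the other way, with 60 above and 257 below. Among the 2281 genes above, 812 had a called departure, of which 781 lay nearer to 2 µM. Above the midpoint were CYP26C1 (departure 4.11 ± 0.17 on the log2 scale), DMBX1, CYP26A1, PAX1, PLPPR5 and PCDH8. In CPM, however, CYP26C1, CYP26A1 and DMBX1 rose by more in the second step than in the first, while PAX1 and PCDH8 did not. Below it were AFP (departure −5.12 ± 0.69, adjusted p = 0.00266), VCAM1, SERPINA1, PRODH2, AKR1D1 and FGG. AFP was near its floor at both 1 and 2 µM, so its departure rests on few counts there. The same limit holds for FGG, with log2 fold changes of −6.74 and −7.75 at 1 and 2 against 0 µM. AKR1D1 had changes of similar size (−6.52 and −6.96). Changes in both steps, which some of the departing genes also had, were called for 266 genes rising in each and 464 falling in each.

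The transcription factor gene NKX2-1 (chromosome 14, 36516392 to 36521149), which marks lung and thyroid progenitors and part of the forebrain, was highest at 1 µM. Its level was 12 ± 0.994 CPM at 0 µM, 28 ± 1.8 at 1 µM and 15.1 ± 1.22 at 2 µM (n = 3 each), a rise (log2 fold change 1.22 ± 0.10, adjusted p = 1.4e-07) and then a fall (log2 fold change −0.89 ± 0.10, adjusted p = 2.2e-05). The EGFP reporter at this gene, chosen like SFTA3 after its values were seen, had 2.25 ± 0.894, 5.88 ± 0.127 and 2.37 ± 0.378 CPM. It rose by 1.38 (adjusted p = 0.000616) and fell by 1.31 (adjusted p = 0.00432) on the log2 scale. The neighbouring gene SFTA3 had 0.72 ± 0.469, 2.49 ± 0.575 and 1.7 ± 0.0821 CPM, and its second step did not pass (adjusted p = 0.514). Between 0 and 2 µM NKX2-1 was called (log2 fold change 0.34, adjusted p = 0.0142), but not without 0 µM replicate 2 (0.0618) or without 2 µM replicate 3 (0.0773), with a range of 0.00577 to 1 over its alternatives. Against a change of 1.5-fold the second step of NKX2-1 and of EGFP did not pass (adjusted p = 0.0672 and 0.112, the highest over their alternatives, from 1.5e-15 and 2.1e-05). In all, 56 genes rose and then fell, among them PCDH8, a protocadherin (4.28 ± 1.24, 24.9 ± 1.52 and 11.2 ± 0.835 CPM), KCNJ3, CD34 (13.7 ± 0.474, 99.7 ± 7.17 and 66 ± 5.17 CPM) and TDGF1. Another 50 fell and then rose, among them AKR1B10 and DDC.

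**Figure D5:**
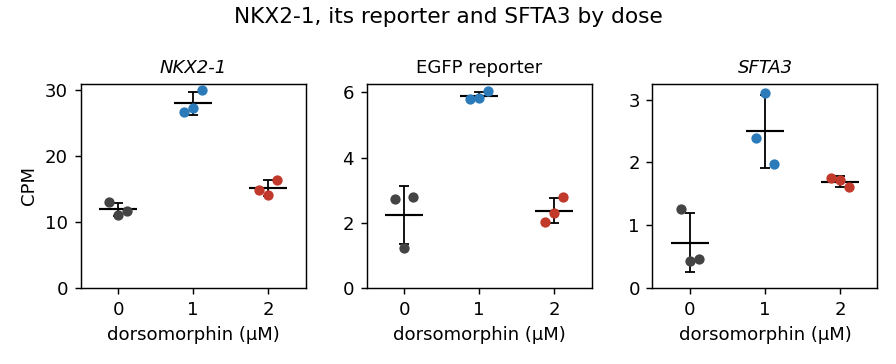
TMM-scaled CPM of NKX2-1, the EGFP reporter and SFTA3 against dorsomorphin dose (0, 1 and 2 µM), with 1 point per library and the mean ± SD of 3 libraries. The means of NKX2-1 are 12, 28 and 15.1 CPM.

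The departure count moved with the libraries used. It was 988 without 1 µM replicate 1, 1112 without 1 µM replicate 2 and 1035 without both 0 µM replicate 1 and 2 µM replicate 2. It was 2599 without 2 µM replicate 1, and 147 genes departed by more than 1.5-fold, 46 of them above and the others below. AFP lost its departure call without 2 µM replicate 1 (adjusted p = 0.0569, with a range of 4.5e-09 to 0.0569 over its alternatives). PAX1 lost its own without 1 µM replicate 1 (0.0540) or 2 µM replicate 1 (0.0559) and with DESeq2 (0.127), with a range of 3.5e-05 to 0.127. It also lost the call without the low-count filter (0.0522) and against a change of 1.5-fold (0.0869). AKR1D1 lost it with limma-voom (0.0581) and without the low-count filter (0.0634), with a range of 1.6e-07 to 0.0634.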

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

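Halved counts and leaving out 0 µM replicate 1 with 2 µM replicate 2 were chosen only after the data were seen. No call changed direction in any alternative run. Over the named genes 11231 comparisons of an alternative with the reported value kept direction and side of the threshold, 402 lost the call, 30 gained one and 24 uncalled values changed sign or moved, and over the lists 795 kept and 72 lost it. Against a change of 1.5-fold (glmTreat) 1467, 2142 and 179 genes were called for 1 against 0, 2 against 0 and 2 against 1 µM and 147 for the departure, by construction of a stricter null. At an adjusted p under 0.01 the counts were 670 for 2 against 1 µM and 969 for the departure. Without both named libraries they were 655 and 1035, with fewer samples. With an estimated correlation 5, 7 and 7 lists were called, and by fry, which compares a list with no other genes, 28 for 1 against 0 µM, where the cause was not tested. Leaving out 1 library in turn gave 4201 to 6972 genes for 1 against 0 µM, 5656 to 7384 for 2 against 0, 756 to 1529 for 2 against 1, 5263 to 7921 over the 3 doses and 988 (without 1 µM replicate 1; 1112 without 1 µM replicate 2) to 2599 (without 2 µM replicate 1) for the departure, and 14 to 17, 17 to 20 and 14 to 20 lists. No pairing by replicate number was seen, with correlations of deviations between −0.161 and 0.108 for same-numbered and between −0.173 and 0.182 for other libraries. The labels do not say whether the numbers pair the samples. With a replicate block 5154, 6308, 945 and 1515 genes were called. Without the low-count filter the median log2 fold change of all genes was −0.11 for 1 against 0 µM. Counts from 1 to 10 were mostly even numbers, so that depth limits genes at such counts further.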

Other observations

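Among the tests of explanations, those of the scaling and of overlapping reads for NKX2-1 were chosen only after the result was seen.

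Several gene groups not described so far moved in part or not at all as groups. Of 14 FGF-ERK target genes 3 rose and 4 fell at 1 against 0 µM (4 and 4 when adjusted over the list alone) and 7 rose and 4 fell at 2 against 0 µM, also when adjusted over the list alone, with the list uncalled (camera adjusted p = 0.0794 and 0.376). The phosphatase gene DUSP5 fell from 123 ± 14.7 CPM at 0 µM to 15.4 ± 1.32 at 1 µM (n = 3) and 8.58 ± 1.34 at 2 µM, and DUSP4 from 164 ± 16.5 to 42.2 ± 0.509 and 33.1 ± 2.29, while DUSP6 rose from 4.44 ± 0.674 to 14.7 ± 0.352 CPM at 1 µM and the feedback inhibitor gene SPRY1 from 6.1 ± 0.594 to 24.9 ± 1.55 CPM at 2 µM. Among 13 epithelial junction genes 1 rose and 7 fell at 2 against 0 µM (2 and 7 when adjusted over the list alone, camera adjusted p = 0.0641). KRT19 fell from 3757 ± 362 to 1519 ± 162 CPM and CLDN3 from 104 ± 8.35 to 43.8 ± 3.94 CPM. In the nodal and TGF-beta list 2 rose and 3 fell of 11 (also when adjusted over the list alone, camera adjusted p = 0.879), with CCN2 going from 16.7 ± 1.28 to 70.6 ± 8.55 CPM. Among 9 paraxial mesoderm genes 3 rose and 1 fell (4 and 1 when adjusted over the list alone, camera adjusted p = 0.144), with FOXC1 going from 47.1 ± 3.11 to 219 ± 3.36 CPM. Among 10 neural crest genes 3 rose and 4 fell (also when adjusted over the list alone, camera adjusted p = 0.565), and SNAI2 went from 7.44 ± 1.45 to 0.258 ± 0.0487 CPM.

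For stress and metabolism at 2 against 0 µM, the glycolysis and hypoxia list had 6 rises and 4 falls among 17 (also when adjusted over the list alone, camera adjusted p = 0.967), with the glucose transporter genes SLC2A1 up from 134 ± 5.37 to 269 ± 21.8 CPM and SLC2A3 down from 2412 ± 134 to 1357 ± 39.7 CPM. The p53 target list had 3 rises and 2 falls among 13 (3 and 3 when adjusted over the list alone, camera adjusted p = 0.165), the stress and unfolded protein list 6 and 5 among 15 (7 and 5 when adjusted over the list alone, camera adjusted p = 0.420), and the cholesterol synthesis list 4 and 3 among 18 (also when adjusted over the list alone, camera adjusted p = 0.967). The mesenchyme and matrix list had 4 rises and 2 falls among 14 (also when adjusted over the list alone, camera adjusted p = 0.119). Of 4 measured anterior HOX genes edgeR called 0 at 2 against 0 µM, also when adjusted over the list alone (camera adjusted p = 0.984), with 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. At 1 against 0 µM 1 of the 4 fell, HOXA3 with 0.23 ± 0.148 CPM and then 0 counts in each 1 µM library (1 when adjusted over the list alone, camera adjusted p = 0.706), a call lost without both 0 µM replicate 1 and 2 µM replicate 2 (adjusted p = 0.0672, with a range of 0.000189 to 0.0672 over its alternatives). At 2 against 1 µM edgeR called 0 (2 up when adjusted over the list alone, camera adjusted p = 0.421), with 2 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. Median, mean and test differed in sign for some lists. At 1 against 0 µM the lung and thyroid list had a median of −0.20, a mean of 0.27 and a test direction of up, the esophageal list a median of −0.50 with a direction of up, the mesenchyme list a median of −0.20 with a direction of up, the pluripotency list a median of 0.21 and a mean of −0.03, the nodal list a median of −0.26 and a mean of 0.04, and the immediate early list a median of 0.09 and a mean of −0.42. The FGF-ERK list had a positive median and a negative mean at both doses (0.14 and −0.22, then 0.23 and −0.09). At 2 against 0 µM the same held for the immediate early list (0.34 and −0.07) and the glycolysis list (0.12 and −0.01), while the pluripotency list had a median of −0.17 with a direction of up.

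NKX2-1 and the EGFP reporter were highest at 1 µM. The choice of scaling did not account for this, since with library totals or RLE factors the smaller change of NKX2-1 stayed at 0.87 on the log2 scale. The TMM factors lay only between 0.953 and 1.03, so this test could hardly have come out otherwise. It cannot exclude a scaling error that these methods share. Reads of overlapping or antisense genes at that locus stay open, since the steps of the reporter (at least 1.31 each) are part of the pattern itself. Whether lung and thyroid genes, or neuroectoderm genes, peaked at 1 µM as a set stays open, since camera, a test of limma over the genes of a list (n = 12 measured genes in each, NKX2-1 itself left out), gave p = 0.658 and p = 0.434 on the departure. The lists had medians of −0.10 and 0.02, with 2 members called above and 2 below in the first and 2 above and 0 below in the second. The bound set beforehand against such a set-wide peak, a p of 0.05 or more, was met by both lists, but it was a wrong bound, and it was set aside after the values were seen, since a missed threshold over members that go both ways excludes nothing. 

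More genes were detected in 0 µM replicate 1 (29248) than in any other library. Sequencing depth is argued against, since thinned to the smallest total it still had 1.07 times the genes of the next library. An evenly spread background such as genomic DNA may contribute, since the 382 olfactory receptor genes had 52.6 CPM there, 1.54 times the next library, which is barely past the bound of 1.5 set beforehand, and the RNA preparation included removal of DNA per the labels. These genes had 19.67 and 34.11 CPM in 0 µM replicates 2 and 3, 13.15 to 19.16 CPM at 1 µM and 16.61 to 29.72 CPM at 2 µM. Whether such a background adds to the falls of low-count genes at 1 against 0 µM was not tested. Cells of another type stay open, since the 178 low genes with the largest excess held 10.7% of the excess of 17736 low genes, between the bounds of 10% and 50% set beforehand. No other biological explanation was tested.

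CGA and several other placental genes were counted almost only in 2 µM replicate 2. Beside CGA, 9 of 16 listed placental genes were raised there, led by CSH1 (15.9 CPM against at most 0.0921 in the other libraries), PSG4 (14.7 against at most 0.470) and CYP19A1 (12.4 against at most 0.722), and none of the 8 pituitary genes was raised, with POMC at 324 counts there and 347 to 1337 in the other libraries. Placental RNA in this library is therefore a candidate explanation, whether from cells in the culture or from outside it, and which of these is the source was not tested. By a rule chosen after seeing the data (at least 100 counts and 20 times the next library) 11 genes stood out in this library and 0 in each other library. Among the 11 was also HBA2, a haemoglobin gene, with 341 counts against at most 4 in the other libraries. CGB3, CGB5 and CGB8 were among the listed placental genes that were not raised.

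Other splits of the samples were compared with the real groups. For each pair of doses 6 libraries make 10 splits, and 1 of 10, the real one, gave as many genes, which is too few splits for a share under 0.05: the real counts were 5591, 6702 and 1105 genes for 1 against 0, 2 against 0 and 2 against 1 µM and the highest of the other splits 0 by edgeR in each. The same holds for the lists, with 15, 19 and 17 against a highest other of 9, 8 and 7. For the 3 doses together 100 splits were compared, with the real one among them. Only the real one reached its count (6511, highest other 5914). Chance assignment of these libraries to groups is thus argued against, for a difference of some kind among the groups. Chance differences between cultures are not excluded, since the labels do not say that the libraries came from separate differentiations. For the departure 3 of the 100 splits, the real one among them, reached the real count (1795, highest other 3228). The share set beforehand, under 5%, was met, but it does not bear on a departure of 1 µM, so chance stays open there. All 3 splits keep the 0 µM libraries together, as 6 of the 100 do, which points to a structure of the samples, and with those libraries parted the highest counts were 62 for the 3 doses and 177 for the departure. This reading of the departure splits was made after the result was seen.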
